A study of Mus musculus with 24 samples.

How the data were processed

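Poly(A) RNA from co-cultures of mouse bone-marrow-derived macrophages with spleen lymphocytes of B16-F10-OVA tumour-bearing mice was sequenced by the authors, who extracted it with Trizol. The deposited table held raw counts per Ensembl mouse gene for 24 libraries, 1 column each, which the authors had made from reads trimmed with fastp (version not stated), with GRCm39 as the genome build; the aligner, counter and annotation release were not stated in the sources used here. The values were checked to be whole numbers without scaling. No coordinates are given, because the annotation at hand was for an earlier build. Gene symbols were matched by Ensembl identifier, the length of the longest transcript per gene came from GENCODE vM21, and RefSeq on GRCm38.p6 gave the order of genes along chromosomes and nothing else. Of 55487 gene identifiers 346 had no symbol (0.0228% of counts).

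The groups came from the sample titles. The genotype field of 11 of the 12 knockout samples named other, consecutively numbered genes, whereas the titles and the study design name Tmem175 in all 12. Of the 24 libraries none was left out. The 8 groups of 3 libraries gave 13 comparisons: knockout against WT in 4 conditions, antigen against none in 2 genotypes, each cytokine added to antigen in 2 genotypes, and 3 differences of responses between genotypes. The labels give no sequencing batch or date.

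Genes were kept with edgeR's filterByExpr (14099 genes, 99.9% of counts), libraries were scaled with TMM factors, and a quasi-likelihood model (edgeR 4.0.16 in R 4.3.3, robust fit) was fitted to all 24 libraries with 1 coefficient per group, leaving 16 residual degrees of freedom. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, with no minimum fold. CPM values use the TMM factors. A group mean below 3 counts per library was treated as at the floor, and CPM values are given in place of a fold there. The depth of 17744540 to 24898552 counts per library went with a common biological coefficient of variation of 5.01% between replicates. On simulated counts with these depths and spreads, 38%, 72%, 84% and 96% of genes with true folds of 1.2, 1.5, 2 and 4 were found in a comparison of 3 with 3 libraries, with 3.95% false calls, and 16%, 68%, 76% and 94% for a difference of responses, with 3.85% false calls. These counts were drawn gene by gene around the WT_Ag means. In them 50 genes were changed at each fold, and a rise was also planted in 27 lysosomal genes. The simulated counts held no deviation shared by the genes of a library, so error rates in the real libraries can differ.

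Gene lists of cell type markers and of cellular programs, 35 in all with 539 genes (1 not found), were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01. Adjustment was over the 33 lists with at least 5 tested genes; the erythroid and melanoma lists had 2 and 1 tested genes and were not tested as groups. Calls within a list were also counted after adjustment over the list alone. Of 116 list calls over the 13 comparisons 8 held with a correlation estimated from the data. Several tests of explanations were chosen after the results were seen, as said where they are given. The comparisons, the tests of genes and of lists, the gene lists and the rule for naming genes were chosen before the data were examined. That rule allowed 18 genes of interest, the 8 highest and 8 lowest called genes per comparison (5 and 5 for differences of responses) with a mean of at least 2 log2 CPM and no overlap between groups, and up to 4 called members per list. Of the genes it allowed, the text mostly names those that kept their call under the alternatives, a choice made after the values were seen; of the 18, Il2 and Pdcd1 had too few counts to be tested. Genes outside the rule are said to be so where they are named. A few genes that the rule allowed are not reported here.

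The alternatives were DESeq2's median-of-ratios factors, DESeq2 1.42.0's Wald test, no filter on low counts, a replicate block, a fit of the compared libraries alone, each library left out in turn, and for the lists an estimated correlation and fry. Removing a trend with transcript length from each library, and leaving out immunoglobulin genes, were added after the data were seen. Median-of-ratios factors moved the median of all genes by less than 0.1 on the log2 scale in each comparison and flipped no called list's median. Other splits of the same libraries were tested for every comparison, all 10 for groups of 3 against 3, and for differences of responses 100 with the real one included, the others drawn at random. The seed of these draws and of the random draws of gene pairs was changed once after a first run, for a reason of number printing alone, and the later draws are the ones reported. No verdict differed, although 3 of 100 splits had reached the count for the antigen response in the first draw in place of 2. For the test of 1 lymphocyte pool in both genotypes, the spread with 1 library left out was added after the value was seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.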

Results

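RNA was sequenced from 24 co-cultures of macrophages and lymphocytes, 3 in each of 8 groups. Bone-marrow-derived macrophages, WT or Tmem175-/- (knockout), were kept with spleen lymphocytes of mice bearing B16-F10-OVA tumours, a mouse melanoma line that carries ovalbumin. Each genotype was sampled without antigen (WT_none, KO_none), with B16-F10-OVA tumour cell antigen (WT_Ag, KO_Ag), and with antigen plus IL-1β or IL-18 at 500 pg/ml (WT_Ag_IL1b, WT_Ag_IL18, KO_Ag_IL1b, KO_Ag_IL18). The libraries held 17744540 to 24898552 counts each. Of the 55487 genes listed, 14099, with 99.9% of all counts, had enough counts to be tested. The labels do not say whether the 3 replicates of a group are separate mice, macrophage preparations or wells, so the p-values measure the spread between these samples only. Levels are given as CPM, counts scaled by library size (mean ± SD of 3 libraries), and differences as log2 fold change ± SE, with p adjusted by Benjamini-Hochberg from edgeR's quasi-likelihood test.

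Tmem175, which encodes a lysosomal cation channel, was lower in every knockout library than in any WT library of the same condition, but its RNA was not lost. Without antigen it stood at 26.1, 25.5 and 24.4 CPM in the WT libraries and at 15, 14.1 and 14.6 in the knockout libraries, 1.73-fold lower (log2 fold change -0.79 ± 0.0731, adjusted p 3.74e-09). With antigen the values were 13.7, 16.3 and 15.7 CPM in WT and 7.61, 8.75 and 8.12 in knockout. With antigen and IL-1β they were 15.5, 16 and 15.9 against 8.18, 9.24 and 8.45, and with antigen and IL-18 12.8, 16 and 14.6 against 7.83, 8.8 and 8.13. The log2 fold changes in these 3 conditions were -0.91, -0.87 and -0.82. Antigen itself lowered Tmem175, by a log2 fold change of -0.73 ± 0.0726 in WT and -0.84 ± 0.0835 in knockout cultures. The fall did not differ detectably between genotypes (adjusted p 0.622). Gene counts show neither which part of the transcript remains nor whether its RNA came from the macrophages or from the lymphocytes, whose genotype the labels do not give. T cell RNA was scarce beside macrophage RNA in all groups, as given under other observations, but no library held lymphocytes alone.

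The libraries fell into 4 clusters, by genotype and by antigen, with the cytokine groups inside the antigen clusters. The first principal component, 56.6% of the variance, followed antigen, and the second, 29%, followed genotype. The chi-square per degree of freedom between replicates of a group ran from 1.47 to 16.7 over 24 pairs, highest for KO_none replicates 1 and 2.

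**Figure D1:**
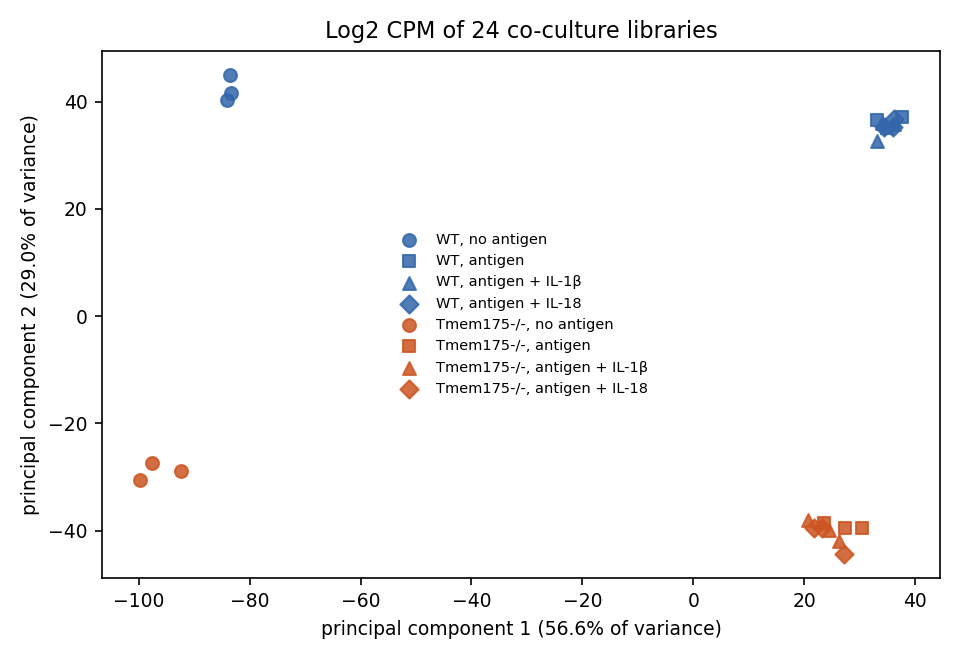
Principal components of log2 CPM in the 24 libraries; the x axis is component 1 (56.6% of variance), the y axis component 2 (29%), colour gives the macrophage genotype and marker shape the condition. Libraries without antigen lie on the left and those with antigen on the right, WT libraries lie above knockout libraries, and the IL-1β and IL-18 groups overlap the antigen groups.

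Without antigen, knockout cultures held far more immunoglobulin RNA than WT cultures. Igkc, the constant region of the kappa light chain, stood at 694 ± 125 CPM against 13.9 ± 3 (log2 fold change 5.64 ± 0.266, adjusted p 1.26e-10). Jchain, which joins the units of secreted IgM and IgA, stood at 191 ± 26.4 against 8.46 ± 1.03 CPM. Of 182 tested immunoglobulin genes 178 were higher and 1 was lower. Slpi, a secreted inhibitor of serine proteases, was 6.93-fold higher. Cd4, the co-receptor of helper T cells, stood at 10.4 ± 0.735 CPM against 44.8 ± 2.27 in WT (log2 fold change -2.10 ± 0.0725, adjusted p 1.9e-18). Since RNA of the T cell genes Cd3e and Trac was far scarcer in all groups, the Cd4 difference does not show fewer helper T cells. The scavenger receptors Marco and Cd163 were 8.64-fold and 3.45-fold lower. The adhesion molecule Vcam1 was 3.73-fold lower, the endosomal protein Wdfy1 3.49-fold, Plxdc2 4.07-fold and the membrane skeleton gene Epb41l3 3.23-fold. Lyz2, the macrophage lysozyme, stood at 6080 ± 178 CPM against 11300 ± 333. The macrophage surface gene Adgre1 stood at 1450 ± 94.4 against 1650 ± 8.12 (log2 fold change -0.19 ± 0.0391, adjusted p 0.000632).

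Killing genes were lower in the same knockout cultures, though T cell RNA was scarce and the counts do not show which cells carried these transcripts. Granzyme B (Gzmb) stood at 13.5 ± 0.286 CPM against 45 ± 2 in WT (log2 fold change -1.74 ± 0.159, adjusted p 3.4e-07). The pore-forming perforin gene Prf1 stood at 0.852 ± 0.0987 against 2.18 ± 0.537 CPM. Of 13 cytotoxic effector genes 7 were lower and 1 was higher (9 and 1 adjusted over the list alone). Their median log2 fold change was -1.075 (camera adjusted p 6.25e-06; adjusted p = 0.0317 with an estimated correlation). Genes of cell division were slightly lower, 18 of 24 with 1 higher (20 and 1 adjusted over the list alone), including Cdc20 at -0.42 and Ccnb1 at -0.40. The list had a median of -0.27 (adjusted p 4.06e-13; adjusted p = 0.0317 with an estimated correlation). Of 9 plasma cell markers 6 were higher (7 adjusted over the list alone; list adjusted p 3.04e-06; adjusted p = 0.0317 with an estimated correlation). Among them were the endoplasmic reticulum genes Mzb1, 1.08 ± 0.268 against 0.0325 ± 0.0281 CPM, and Derl3, 1.17 ± 0.157 against 0.229 ± 0.143 CPM.

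Lysosomal genes were slightly higher as a group without antigen. Of 27 genes 18 were higher and none lower (27 adjusted over the list alone), among them the protease gene Ctsl at a log2 fold change of 0.64 ± 0.0785 and Naglu, an enzyme of heparan sulfate breakdown, at 0.32 ± 0.0461. The list median was 0.21 (camera adjusted p 4.97e-15; adjusted p = 0.0732 with an estimated correlation). Of 20 autophagy genes 6 were higher, with Gabarapl1, a gene of autophagosome maturation, at 0.30 (list adjusted p 0.00443; adjusted p = 0.305 with an estimated correlation). Among 14 lysosomal ion channel genes 6 were higher, including Tpcn2 at 0.40, P2rx4 at 0.19 and Mcoln1 at 0.20, but the list missed the threshold (adjusted p 0.0553; 0.305 with an estimated correlation).

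Inflammatory genes were lower without antigen at a level at which single libraries decided several calls. Of 20 NF-kB target genes 11 were lower (13 adjusted over the list alone), including Nfkbiz, which encodes a nuclear regulator of NF-kB, at -0.85 ± 0.122. The list median was -0.60 (camera adjusted p 3.57e-08; adjusted p = 0.179 with an estimated correlation). The type I interferon list (9 of 20 lower, median -0.62) and the interferon gamma list (4 of 20 lower, median -0.76) passed with adjusted p of 5.74e-08 and 6.42e-09 (adjusted p = 0.322 and adjusted p = 0.305 with an estimated correlation). So did the fibroblast marker list, 6 of 10 lower with a median of -1.52 (adjusted p 0.000111; adjusted p = 0.315 with an estimated correlation). The inflammasome cytokine gene Il1b stood at 2.39 ± 1.54 CPM against 7.51 ± 5 in WT (-1.69 ± 0.433, adjusted p 0.0118). That call was lost without WT_none replicate 2 (0.0825), KO_none replicate 1 (0.0687) or KO_none replicate 3 (0.0587) and with the fit of these 6 libraries alone (0.261). Tnf at -0.66 ± 0.195 (adjusted p 0.026) was lost without WT_none replicate 2 (0.0958) or 3 (0.0553) and without KO_none replicate 1 (0.0978) or 3 (0.122). The inflammasome sensor gene Nlrp3 at -0.53 ± 0.112 (adjusted p 0.0024) kept its call without any 1 library and lost it with the 6 libraries alone (0.214). Casp1, the protease that matures IL-1β and IL-18, and Il18bp, the IL-18 antagonist, showed no detectable difference (-0.07 and -0.24, adjusted p 0.656 and 0.662). Without KO_none replicate 2, however, both were lower (-0.26 and -0.97, adjusted p 5.77e-06 and 1.37e-06). Il18 and its relative Il1rn, the IL-1 receptor antagonist, did not differ detectably (adjusted p 0.882 and 0.3).

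In total 2379 genes differed between genotypes without antigen, 1357 higher and 1022 lower in knockout (1146 and 999 without immunoglobulin genes). Of the 2379 genes, 262 were higher and 318 lower by at least 2-fold. Of 33 gene lists 12 passed, 9 of them whichever 1 library was left out. The T cell marker list was lost without KO_none replicate 2 (adjusted p 0.0753), and the MHC class I and antigen-presenting cell costimulation lists without KO_none replicate 1 (0.164 and 0.0718). All 3 were lower, with medians of -0.11, -0.16 and -0.15, and with an estimated correlation their adjusted p were 0.413, 0.464 and 0.25.

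With antigen, knockout cultures again held more immunoglobulin RNA, with 178 of 182 genes higher, and had less RNA of Fn1, Postn and Col4a1. Igkc stood at 835 ± 79.8 CPM against 16.3 ± 4.13 in WT (log2 fold change 5.69 ± 0.264) and Jchain at 145 ± 9.46 against 6.08 ± 1.58 CPM. Lrmda, linked to melanocyte differentiation, stood at 15.6 ± 0.765 against 1.51 ± 0.397 CPM (3.38 ± 0.126, adjusted p 1.35e-17). Fibronectin (Fn1) stood at 15.4 ± 0.799 against 63.9 ± 11.9 CPM (-2.05 ± 0.265, adjusted p 3.28e-05), and the matrix genes Postn and Col4a1 at log2 fold changes of -2.35 and -2.19. Fibroblast markers moved with them. Of 10 markers 7 were lower, with a median of -1.75, among them Pdgfra at -2.09 and Col1a1 at -1.89 (list adjusted p 5.3e-06; adjusted p = 0.379 with an estimated correlation). Marco stood at 317 ± 48.5 against 1500 ± 130 CPM (-2.24 ± 0.12, adjusted p 5.93e-10), Lyz2 at 6850 ± 768 against 14800 ± 532, and Cd4 at 4.95 ± 0.42 against 16.3 ± 1.64 CPM. The mannose receptor gene Mrc1 was 1.59-fold higher and the fatty acid transporter gene Cd36 1.56-fold higher.

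Cell division genes were higher in knockout cultures with antigen. Of 24 genes 23 were higher (23 adjusted over the list alone), including the cyclin Ccnb2 at 17.2 ± 1.28 against 9.84 ± 0.154 CPM (0.80 ± 0.0766, adjusted p 7.12e-09), Birc5 at 0.69 and Rrm2, a subunit of ribonucleotide reductase, at 0.71. The list median was 0.42 (camera adjusted p 7.26e-24; adjusted p = 0.00303 with an estimated correlation). NF-kB targets were lower in 8 of 20 (11 adjusted over the list alone; median -0.27, adjusted p 1.5e-08; adjusted p = 0.231 with an estimated correlation). The cytokine gene Il6 was 2.35-fold and the neutrophil chemokine gene Cxcl1 2.05-fold lower. Il12b, a subunit of IL-12 and IL-23, was 3.1-fold lower and Il1a 1.29-fold lower. Il1b stood at 385 ± 19.7 against 764 ± 30 CPM (-0.99 ± 0.193, adjusted p 0.00176; DESeq2 0.0767). Il1rn stood at 237 ± 32.8 against 147 ± 5.03 CPM (0.68 ± 0.111, adjusted p 0.000326). Il18, Il18bp, Casp1 and Tnf did not pass (adjusted p 0.67, 0.71, 0.615 and 0.434), nor did Nlrp3 at -0.20 (0.225), which passed from the 6 compared libraries alone (0.00493). Granzyme A (Gzma) was 2.35-fold higher, whereas Gzmb at 44.3 ± 4.34 against 34.1 ± 6.37 CPM did not pass with all libraries (adjusted p 0.0773). It passed without WT_Ag replicate 3 (0.0187) and with DESeq2 (0.032), among other settings.

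The lysosome list was higher with antigen in 11 of 27 genes with 1 lower (median 0.10, camera adjusted p 0.00201; adjusted p = 0.572 with an estimated correlation), with the collagen-degrading protease gene Ctsk at 0.83 ± 0.197. Plasma cell markers were higher in 5 of 9 with 1 lower, including the transcription factor gene Irf4 at 1.14 ± 0.142 (list adjusted p 0.000979; adjusted p = 0.181 with an estimated correlation). The glycolysis and hypoxia list was lower with 2 of 18 genes passing, including Ankrd37 at -0.71 (adjusted p 0.000472; adjusted p = 0.572 with an estimated correlation). Dendritic cell markers, with the actin bundling gene Fscn1 at -1.53, passed with all libraries (list adjusted p 0.0192; adjusted p = 0.154 with an estimated correlation) but not without KO_Ag replicate 1 (0.0577). The same held for the cholesterol synthesis list (0.00201; 0.133 without that library; adjusted p = 0.572 with an estimated correlation). The list of type 2 and type 17 T cell genes, 3 of 5 lower (0.0469; adjusted p = 0.181 with an estimated correlation), was lost without KO_Ag replicate 1, 2 or 3 (0.231, 0.301, 0.269), and without WT_Ag replicate 1 or 2 (0.328, 0.266). In all, 2160 genes differed, 1085 higher and 1075 lower (882 and 1052 without immunoglobulin genes), of which 259 and 304 by at least 2-fold. Of the lists 9 passed, 6 of them whichever 1 library was left out.

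With IL-1β or IL-18 added to the antigen, Igkc and the neutrophil genes Ltf and Ngp were higher in knockout cultures, and Marco, Il1b and Col4a1 were lower. With IL-1β, Igkc, Jchain and Lrmda were higher at log2 fold changes of 5.71, 4.72 and 2.98, and Marco, Col4a1, Wdfy1 and Lyz2 were lower at -2.09, -2.01, -1.87 and -0.90. With IL-18 the same 4 lower genes stood at -1.90, -2.12, -1.75 and -0.87, and Fn1 at -1.92. The neutrophil granule genes Ltf (lactoferrin) and Ngp were 6.2-fold and 2.67-fold higher with IL-1β, and 5-fold and 2.71-fold higher with IL-18. Their levels were 4.64 ± 0.981 and 40.9 ± 7.61 CPM in KO_Ag_IL1b. Of 13 neutrophil markers 8 were higher with IL-1β and 7 with IL-18 (list adjusted p 4.95e-07 and 2.77e-06; adjusted p = 0.0652 and adjusted p = 0.0908 with an estimated correlation). Il1b was lower in both conditions. It stood at 490 ± 57 against 915 ± 81.9 CPM with IL-1β (-0.90 ± 0.192, adjusted p 0.00395; DESeq2 0.129) and at 428 ± 34.1 against 809 ± 5.43 with IL-18 (-0.92 ± 0.192, adjusted p 0.00274; DESeq2 0.0857). Il1rn was higher at 0.45 ± 0.111 with IL-1β (adjusted p 0.0102) and 0.52 ± 0.112 with IL-18 (adjusted p 0.00302, and 0.0755 from the 6 compared libraries alone).

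Cell division genes were higher in 21 of 24 with either cytokine, with Ccna2 1.51-fold and 1.49-fold higher (list adjusted p 7.52e-20 and 5.07e-15; adjusted p = 0.00767 and adjusted p = 0.0275 with an estimated correlation). NF-kB targets were lower in 11 and 10 of 20, with Il6 2.34-fold and 1.95-fold lower (adjusted p 6.57e-13 and 3.41e-08; adjusted p = 0.0978 and adjusted p = 0.193 with an estimated correlation). Glycolysis and hypoxia genes were lower in 6 and 7 of 18, with Ankrd37 at -0.61 and -0.48 (adjusted p 9.33e-09 and 1.57e-06; adjusted p = 0.275 and adjusted p = 0.392 with an estimated correlation). Fibroblast markers were lower in 7 of 10 in both (adjusted p = 0.275 and adjusted p = 0.317 with an estimated correlation). Plasma cell markers were higher in 6 of 9 with 1 lower in both (adjusted p = 0.0558 and adjusted p = 0.0908 with an estimated correlation). Lysosomal genes were higher in 9 and 13 of 27 with 1 lower each, with Ctsk 1.83-fold and 2.16-fold higher (adjusted p 0.000627 and 6.24e-06; adjusted p = 0.386 and adjusted p = 0.316 with an estimated correlation). With IL-18, 7 of 11 MHC class II genes were higher and 1 lower, the invariant chain gene Cd74 being 1.9-fold higher (list adjusted p 0.00251; adjusted p = 0.414 with an estimated correlation).

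With IL-1β 1941 genes differed between genotypes, 1018 higher and 923 lower (806 and 893 without immunoglobulin genes). With IL-18 there were 2851, 1395 higher and 1456 lower (1188 and 1433 without immunoglobulin genes). Without WT_Ag_IL18 replicate 3 this count was 1867. Higher genes were the more numerous with IL-18 without WT_Ag_IL18 replicate 1 (1128 and 996), KO_Ag_IL18 replicate 1 (1110 and 1085) or KO_Ag_IL18 replicate 3 (1249 and 1042), and with a trend with transcript length removed (1287 and 1248). In the IL-18 condition the log2 fold changes fell with transcript length (Spearman -0.222 across genes, which are not independent replicates). The values were -0.138 with IL-1β, -0.148 with antigen alone and -0.0612 without antigen. Of the lists, 13 passed in each condition, 9 with IL-1β and 8 with IL-18 whichever 1 library was left out, and 1 in each, cell division, held with an estimated correlation. With IL-1β the mast cell, platelet and MHC class II lists were higher and the p53 list lower (adjusted p = 0.255, adjusted p = 0.48, adjusted p = 0.563 and adjusted p = 0.275 with an estimated correlation). The 4 were lost without KO_Ag_IL1b replicate 1 (adjusted p 0.0585, 0.151, 0.068 and 0.172). Platelet and p53 were lost also without KO_Ag_IL1b replicate 3 (0.0807 and 0.0746) or WT_Ag_IL1b replicate 2 (0.0865 and 0.0975). With IL-18 the cytotoxic, macrophage, mast cell and platelet lists were higher and the p53 list lower (adjusted p = 0.316, adjusted p = 0.629, adjusted p = 0.193, adjusted p = 0.41 and adjusted p = 0.193 with an estimated correlation). The cytotoxic list was lost without KO_Ag_IL18 replicate 1 or 3 (0.0977, 0.0839) or WT_Ag_IL18 replicate 1 or 2 (0.0635, 0.0758). The macrophage list was lost without KO_Ag_IL18 replicate 2 or 3 (0.151, 0.0606) or WT_Ag_IL18 replicate 1 or 3 (0.128, 0.0647). The mast cell, p53 and platelet lists were each lost without WT_Ag_IL18 replicate 2 (0.0595), the last also without KO_Ag_IL18 replicate 1 (0.0593).

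Across the 4 conditions 365 genes were higher in knockout each time and 233 lower, against 0.7 and 0.5 for independent calls. Of these 598 genes 175 were immunoglobulin genes, and 190 of the higher genes were not. Variable segments of immunoglobulin genes summed to 1260 to 2210 CPM in the 12 knockout libraries and to 32.9 to 57.5 in the 12 WT libraries. Without and with antigen, 431 genes were higher and 350 lower in both (104.4 and 77.9 for independent calls), and 147 were called in opposite directions. The log2 fold changes had a Pearson r of 0.835 across genes, which are not independent replicates. The genotype comparisons set the same WT and knockout arms against each other. The labels do not say whether the conditions of an arm shared macrophage preparations or lymphocytes. A difference between the arms, whether from genotype or from the cells used, could recur in each condition. Independent calls are therefore no null for these overlaps.

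**Figure D2:**
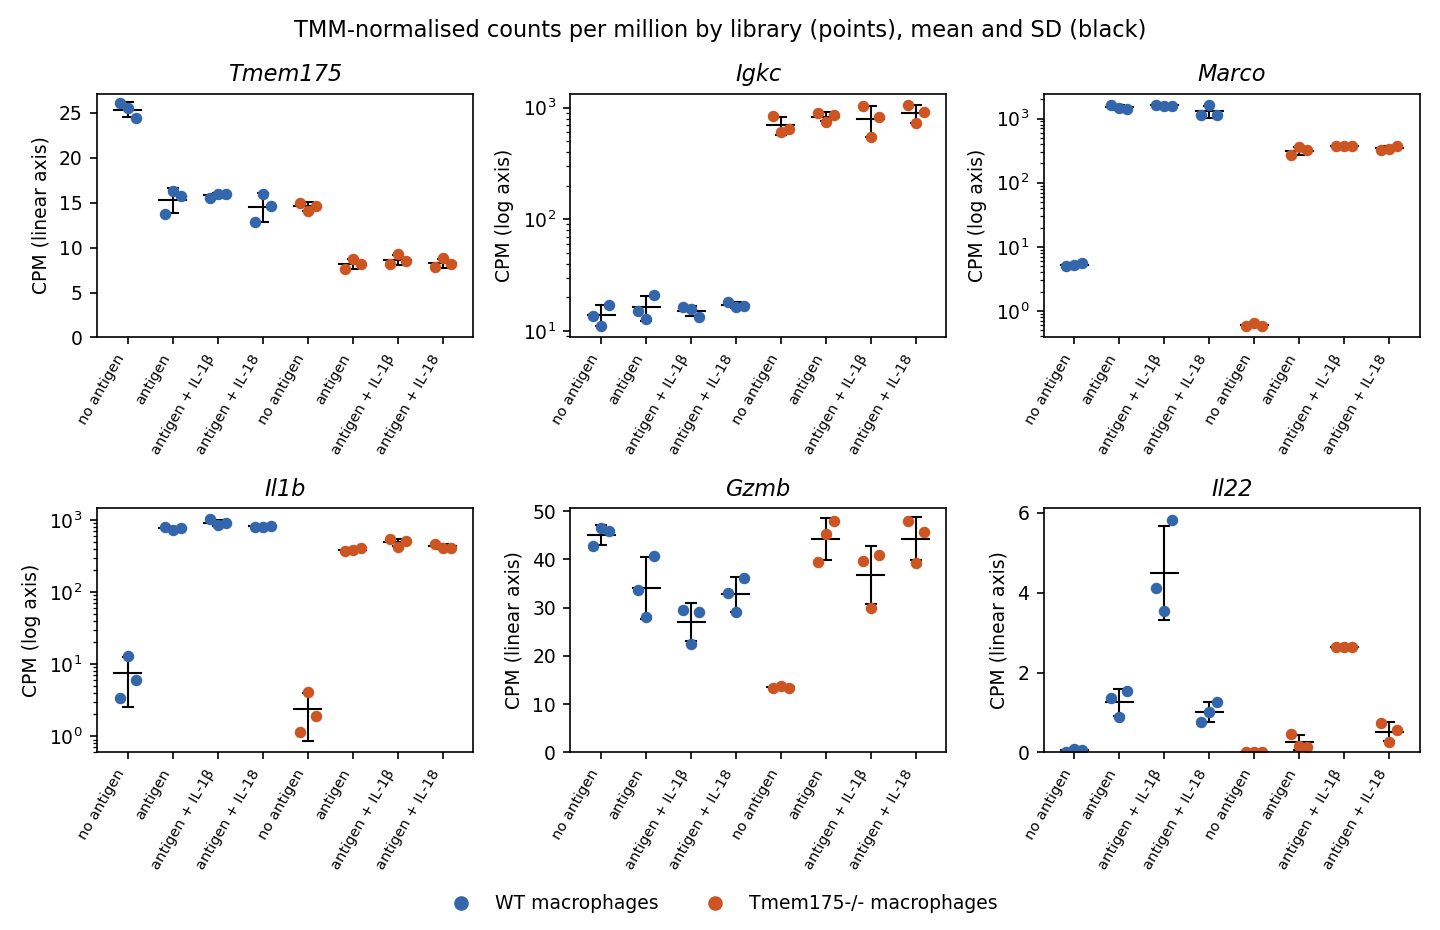
CPM of 6 genes (Tmem175, Igkc, Marco, Il1b, Gzmb, Il22) in the 8 groups on the x axes; points are libraries, black marks the mean and SD of 3 libraries, and the y axes of Igkc, Marco and Il1b are logarithmic. Tmem175 and Marco are lower and Igkc is higher in knockout in each condition, Gzmb goes from 13.5 to 44.3 CPM with antigen in knockout and from 45 to 34.1 in WT, and Il22 is highest with IL-1β (4.49 CPM in WT, 2.63 in knockout).

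Antigen changed most of the measured transcriptome of WT cultures. The acute phase gene Saa3 went from 8.74 ± 6.93 to 19200 ± 349 CPM (log2 fold change 11.10 ± 0.404, adjusted p 6.31e-14) and Marco from 5.25 ± 0.322 to 1500 ± 130 CPM (8.15 ± 0.174). The ectoenzyme gene Cd38 went from 3.57 ± 0.23 to 532 ± 15.7 (7.22 ± 0.0669, adjusted p 1.8e-33) and Il1b from 7.51 ± 5 to 764 ± 30 (6.66 ± 0.271, adjusted p 3.18e-13). The nitric oxide synthase gene Nos2 went from 1.52 ± 1.61 to 661 ± 69.8 CPM. The carboxylate transporter gene Slc13a3 rose by 8.06 on the log2 scale. The organic anion transporter gene Slco2b1 fell from 99.2 ± 8.47 to 0.48 ± 0.244 CPM and Mamdc2 from 171 ± 4.66 to 1 ± 0.186. Dcstamp, required for macrophage fusion, fell from 45.2 ± 4.44 to 0.337 ± 0.0406, and Ltf from 103 ± 12.2 to 1.12 ± 0.0936. Other cytokine genes rose as well. Il18 rose by 1.04 ± 0.121, Il18bp by 2.07 ± 0.264, Il1rn by 0.90 ± 0.116, Tnf by 1.73 ± 0.158 and Nlrp3 by 0.50 ± 0.106 on the log2 scale. Casp1 did not pass (-0.09 ± 0.0829, adjusted p 0.337; 0.0467 from the 6 libraries alone). Ifng went from 0.473 ± 0.0254 to 2.55 ± 0.247 CPM (adjusted p 1.28e-07). Cd4 had a log2 fold change of -1.46 and Cd8a, the co-receptor of killer T cells, of 0.61 ± 0.175 (adjusted p 0.00312). With T cell RNA scarce in all groups, neither value shows a change in T cell numbers. Gzmb at -0.41 ± 0.14 (adjusted p 0.0163) was lost without WT_none replicate 2 (0.0511) or WT_Ag replicate 2 (0.104) and from the 6 libraries alone (0.0585).

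Whole programs moved with antigen in WT cultures. All 20 NF-kB targets and all 20 type I interferon genes rose (camera adjusted p 9.86e-10 and 8.3e-09). The chemokine gene Cxcl3 stood at 26.6 ± 6.45 against 0.245 ± 0.0982 CPM and the interferon regulator Irf7 at 528 ± 60.3 against 23.2 ± 5.81 CPM. All 18 glycolysis and hypoxia genes rose, among them the lactate exporter gene Slc16a3 8.84-fold and the glucose transporter gene Slc2a1 6.09-fold (adjusted p 5.85e-10). All 18 cholesterol synthesis genes fell, Cyp51 5.41-fold (adjusted p 6.53e-10). All 24 cell division genes fell, with Cenpf 3.69-fold and Pcna 3.23-fold lower (adjusted p 1.11e-12). Of 27 lysosomal genes 17 fell and 6 rose, Atp6v0d2, a proton pump subunit, 16.4-fold and the acid lipase gene Lipa 4.26-fold lower (adjusted p 0.00522). Of 16 MHC class I genes 12 rose and 1 fell, with the peptide transporter gene Tap1 2.97-fold higher (adjusted p 0.00389). The costimulation list (10 of 14 higher, 1 lower; adjusted p 0.00389), the inflammasome list (10 of 16 higher, 2 lower; 0.0204) and the B cell activation list (10 of 13 higher, 3 lower; 0.0369), whose largest change was Cd38, also passed. None of these 10 lists held with an estimated correlation, where adjusted p ran from adjusted p = 0.0552 for cell division to adjusted p = 0.593 for MHC class I.

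Knockout cultures also changed strongly with antigen. Saa3 went from 3.25 ± 2.78 to 18500 ± 1680 CPM and Marco from 0.604 ± 0.0304 to 317 ± 48.5 (9.03 ± 0.226, adjusted p 2.03e-16). Cd38 rose by 7.89 ± 0.0699 and Il1b from 2.39 ± 1.54 to 385 ± 19.7 CPM (7.36 ± 0.312, adjusted p 5.57e-13). Slco2b1 fell from 110 ± 5.77 to 0.308 ± 0.123 and the intermediate filament gene nestin (Nes) from 47.1 ± 5.95 to 0.358 ± 0.208 CPM. Il18, Il18bp, Il1rn, Tnf and Nlrp3 rose by 0.90, 2.48, 1.39, 2.21 and 0.83 on the log2 scale. Casp1 did not pass (0.055, adjusted p 0.568) except without KO_none replicate 2 (0.25, adjusted p 7.64e-07). Gzmb rose from 13.5 ± 0.286 to 44.3 ± 4.34 CPM (1.72 ± 0.158, adjusted p 2.09e-08) and Prf1 by 1.36 ± 0.283 (adjusted p 0.000112). All 20 NF-kB and all 20 type I interferon genes rose (adjusted p 3.94e-09 and 3.99e-10), as did 17 of 18 glycolysis and hypoxia genes (2.6e-09). All 18 cholesterol genes fell (2.74e-10), and 20 of 24 cell division genes fell with 1 higher (2.76e-05). Lysosomal genes fell in 18 of 27 and rose in 5 (0.000178), and MHC class I genes rose in 13 of 16 and fell in 2 (0.000563). The interferon gamma (15 of 20 higher, 2 lower), costimulation (12 of 14 higher, 1 lower) and inflammasome lists (11 of 16 higher, 2 lower) passed with 0.000424, 0.000626 and 0.00337. The cytotoxic list, 9 of 13 higher, passed (0.0352) but not without KO_Ag replicate 2 (0.0576), KO_none replicate 1 (0.0523) or KO_none replicate 2 (0.0544). With an estimated correlation these 11 lists had adjusted p from adjusted p = 0.304 to adjusted p = 0.557.

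Antigen changed 9591 genes in WT (4723 higher, 4868 lower) and 9633 in knockout cultures (4760 higher, 4873 lower), of which 1511 and 1258, and 1544 and 1191, by at least 2-fold. The balance of directions was near even and turned with single libraries or the scaling. In WT it turned without WT_none replicate 2 (4610 higher, 4579 lower), WT_none replicate 3 (4607, 4593) or WT_Ag replicate 3 (4638, 4600), and with DESeq2's size factors (4841, 4761). In knockout it turned without KO_none replicate 1 (4658, 4612), 2 (4776, 4585) or 3 (4604, 4559) and without KO_Ag replicate 1 (4696, 4445) or 2 (4871, 4543). In both genotypes 4083 genes rose and 4210 fell, against 1594.5 and 1682.5 for independent calls, and 48 were called in opposite directions. The log2 fold changes had a Pearson r of 0.922 across genes, which are not independent replicates.

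The antigen response itself differed between genotypes for 1183 genes, most clearly for killing and cell division genes. Gzmb had a response higher by 2.12 ± 0.212 on the log2 scale in knockout (adjusted p 6.04e-06). It went from 13.5 to 44.3 CPM there and from 45 to 34.1 in WT cultures. Prf1, Gzma and Gzmc responded more in knockout by 1.88 ± 0.383, 2.31 and 2.71. They started from 0.852, 1.96 and 0.349 CPM in KO_none against 2.18, 4.18 and 2.75 in WT_none. Of 13 cytotoxic genes 6 had a more positive response in knockout (8 adjusted over the list alone). The median difference was 1.21 (camera adjusted p 5.05e-09; adjusted p = 0.00604 with an estimated correlation). Of 24 cell division genes 23 did so, with a median of 0.75 (adjusted p 6.91e-41; adjusted p = 0.000144 with an estimated correlation). Ccnb2 went from 25.1 to 9.84 CPM in WT and from 20.7 to 17.2 in knockout cultures, and Ccna2 from 67.4 to 22.9 and from 54.7 to 36.3. The monocyte chemokine gene Ccl12 rose from 1.52 to 14.1 CPM in WT and from 0.53 to 25.9 in knockout cultures (difference 2.45 ± 0.556, adjusted p 0.00958), and Rasgrp3, an activator of Ras, fell less in knockout (difference 1.86). Nfkbiz also differed upward, by 0.61.

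For other genes the difference was negative. Fn1 fell from 151 ± 28 to 15.4 ± 0.799 CPM with antigen in knockout and from 126 ± 17.6 to 63.9 ± 11.9 in WT cultures (difference -2.31 ± 0.338, adjusted p 0.000349). Nes fell further in knockout (difference -2.36 ± 0.404), as did the RNA-binding protein gene Samd4 (-1.66) and the growth factor receptor gene Fgfr1 (-1.34). Slpi rose from 1.83 to 56.2 CPM in WT and from 12.7 to 92.8 in knockout cultures (difference -2.07 ± 0.242, adjusted p 2.18e-05). The lysosome list, which mostly fell with antigen in both genotypes, had a more negative response in knockout (7 of 27 genes, median -0.11, camera adjusted p 1.77e-05; adjusted p = 0.454 with an estimated correlation). So had autophagy (6 of 20, median -0.13, 0.000103; adjusted p = 0.257 with an estimated correlation), with Map1lc3a at -0.62. Of the 1183 genes 534 differed upward and 649 downward, 72 and 27 by at least 2-fold. More differed upward than downward without KO_Ag replicate 1 (456 and 378), WT_Ag replicate 3 (465 and 429) or KO_none replicate 2 (863 and 834), and from the 12 compared libraries alone (447 and 357). Of the lists 11 passed, 7 of them whichever 1 library was left out. Il1b, Il18, Tnf and Casp1 responded without a detectable difference between genotypes (adjusted p 0.461, 0.732, 0.271 and 0.534), although Casp1 passed without KO_none replicate 2 (0.33, adjusted p 2.78e-05). Il18bp, Nlrp3 and Il1rn did not pass either (adjusted p 0.597, 0.218 and 0.0791). Without KO_none replicate 2 Il18bp and Nlrp3 passed (1.14 and 0.57, adjusted p 5.92e-06 and 1.7e-06). Il1rn passed with DESeq2 (0.0138), with a replicate block (0.0104) and without KO_Ag replicate 2 (0.0414).

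**Figure D3:**
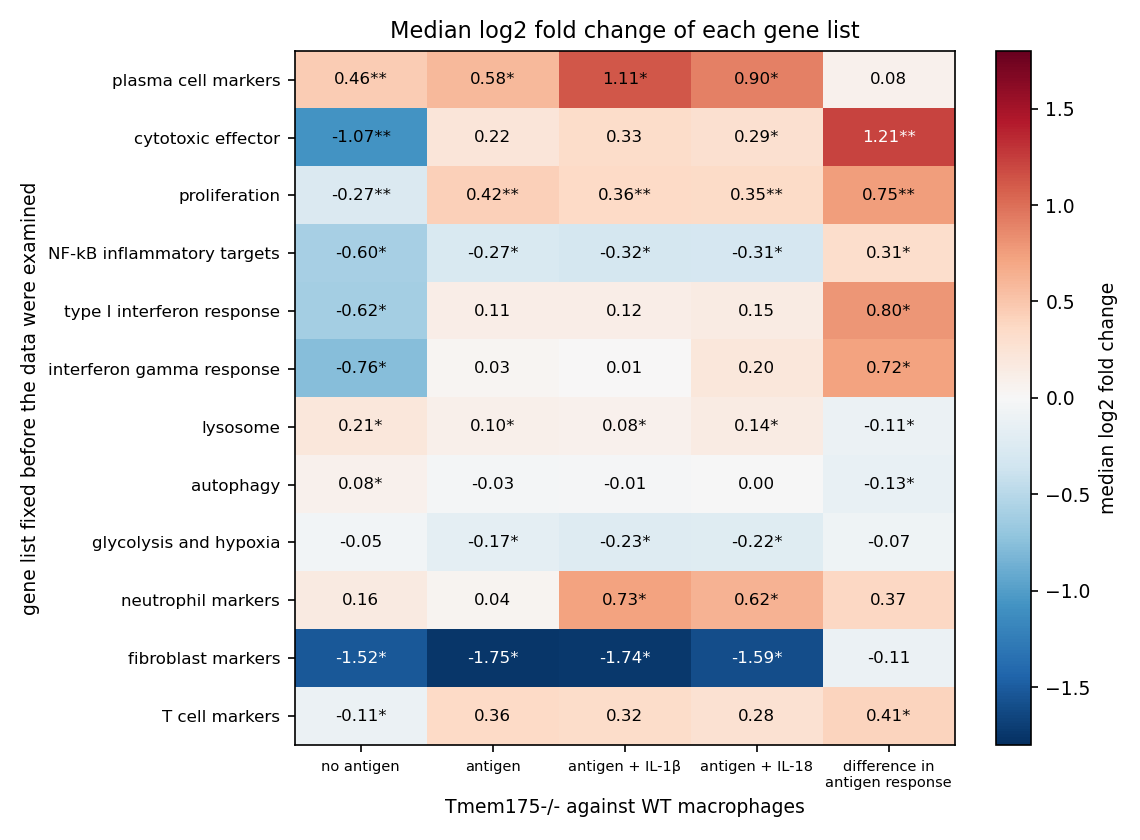
Median log2 fold change of 12 gene lists (y axis) for knockout against WT in the 4 conditions and for the difference in antigen response (x axis); colour and printed value give the median, 1 star marks camera adjusted p under 0.05 and 2 stars those that also hold with an estimated correlation. Cell division genes are lower without antigen (-0.27) and higher in the 3 conditions with antigen, and the cytotoxic list is lower without antigen (-1.075).

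IL-1β added to antigen raised Il22, a cytokine of type 17 and innate lymphocytes. In WT cultures Il22 went from 1.25 ± 0.336 to 4.49 ± 1.19 CPM (log2 fold change 1.85 ± 0.253, adjusted p 0.000722) and Il1a from 45.8 ± 1.98 to 63.3 ± 3.03 CPM (0.47 ± 0.058, adjusted p 0.000133). In knockout cultures Il22 went from 0.25 ± 0.189 to 2.63 ± 0.013 CPM (adjusted p 2.44e-05; DESeq2 gave none). The other calls were 6 genes in WT (Cd164, Csf2rb, Atf5, Bcl6, Tmem176b and Tmem176a) and 5 in knockout (Ptgs1, Rara, Klhl6, Zyx and Cd164), none changed by more than 1.33-fold. Il1b, Il18, Tnf, Ifng and Gzmb did not pass in WT (adjusted p 0.719, 0.655, 0.937, 0.587 and 0.504) or in knockout cultures (0.46, 0.327, 0.79, 0.568 and 0.424). With a replicate block Il18 passed in knockout (log2 fold change 0.243, adjusted p 0.0241).

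The counts of the IL-1β comparisons, 8 genes in WT (1319 at an unadjusted p under 0.05) and 6 in knockout (1882), depended on the settings and on single libraries. DESeq2 gave 8 and 73, and without a filter on low counts there were 79 and 287. In knockout DESeq2 gave an adjusted p to 2495 genes only, and 2 of its 73 calls were among the 6. A replicate block gave 102 in WT and 422 in knockout. In WT the count was 3 without WT_Ag replicate 1, 2 without WT_Ag replicate 3, 2 without WT_Ag_IL1b replicate 2 and 3 without WT_Ag_IL1b replicate 3. Il22 and Il1a kept their calls without any 1 library. In knockout it was 1 without KO_Ag replicate 1 or 3, 284 without KO_Ag replicate 2, 18 without KO_Ag_IL1b replicate 1, 4 without KO_Ag_IL1b replicate 2 and 2 without KO_Ag_IL1b replicate 3. Il22 kept its call each time. Lists moved by little. In WT 6 lists passed, 2 of them whichever 1 library was left out. These were cell division, with a median of 0.10 and no gene called, and the inflammasome list, with a median of 0.08 and 1 of 16 genes called (camera adjusted p 5.45e-05 and 0.000125; adjusted p = 0.494 for both with an estimated correlation). The macrophage, NF-kB and interferon gamma lists were higher and the glycolysis and hypoxia list lower (adjusted p = 0.745 for each with an estimated correlation). Macrophage and glycolysis were lost without WT_Ag replicate 1 (0.0753) or WT_Ag_IL1b replicate 2 (0.0557), NF-kB without WT_Ag replicate 2 (0.0782) or WT_Ag_IL1b replicate 1 (0.0831), and interferon gamma without WT_Ag replicate 2 (0.0684). In knockout macrophage markers had a median of 0.16, neutrophil markers of 0.34 and glycolysis and hypoxia genes of -0.17 with no gene called (adjusted p 1.89e-09, 6.72e-06 and 1.89e-09; adjusted p = 0.495, adjusted p = 0.283 and adjusted p = 0.769 with an estimated correlation). MHC class II and cholesterol synthesis, higher, and endoplasmic reticulum stress, lower, also passed (adjusted p = 0.769 for each with an estimated correlation). Without KO_Ag replicate 1 these 3 were lost (0.201, 0.388 and 0.0777). No gene had a detectably different IL-1β response between genotypes by edgeR (576 at an unadjusted p under 0.05; DESeq2 0), Il22 included (adjusted p 1).

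IL-18 added to antigen changed no gene detectably in WT cultures by edgeR (580 at an unadjusted p under 0.05; DESeq2 0; 1 gene without WT_Ag_IL18 replicate 2). Il1b, Ifng, Gzmb and Tnf had log2 fold changes of 0.08, -0.12, -0.06 and 0.18 with adjusted p of 1. The cell division list had a median of 0.09 with no gene called (camera adjusted p 0.000191; adjusted p = 0.428 with an estimated correlation) and passed whichever 1 library was left out. The B cell, macrophage, interferon gamma and cholesterol lists were lower (adjusted p = 0.428 for B cell and adjusted p = 0.814 for the others with an estimated correlation). All 4 were lost without WT_Ag_IL18 replicate 1 (adjusted p 0.175, 0.333, 0.44 and 0.12). B cell was lost also without WT_Ag replicate 3 (0.178) or WT_Ag_IL18 replicate 2 (0.12), macrophage without WT_Ag replicate 2 (0.302) or WT_Ag_IL18 replicate 3 (0.141), interferon gamma without WT_Ag replicate 1 or 3 (0.104, 0.118) or WT_Ag_IL18 replicate 2 (0.052), and cholesterol without WT_Ag replicate 2 or 3 (0.0723, 0.102) or WT_Ag_IL18 replicate 3 (0.141).

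In knockout cultures with IL-18 added 30 genes changed, 7 higher and 23 lower, none by more than 1.26-fold (1748 at an unadjusted p under 0.05; DESeq2 232). The highest was Spsb3 at 0.33 ± 0.0686 and the lowest Hivep3, which encodes a zinc finger protein, at -0.32 ± 0.0598. The endocytic receptor gene Lrp1 stood at -0.24 ± 0.0411 and the actin regulator gene Coro1a at 0.20 ± 0.0344. The 23 lower genes had long transcripts (median 10546 bases against 2004 for the higher genes and 3160 for all tested genes). No gene was called without KO_Ag replicate 1 or 3 or KO_Ag_IL18 replicate 1 or 3, and 175 and 233 were called without KO_Ag replicate 2 and without KO_Ag_IL18 replicate 2. Neutrophil markers had a median of 0.36 in knockout with no gene called (list adjusted p 3.64e-05; adjusted p = 0.349 with an estimated correlation) and passed whichever 1 library was left out. Macrophage, platelet, MHC class II and cholesterol lists were higher and glycolysis and hypoxia lower (adjusted p = 0.967 for each with an estimated correlation). All 5 were lost without KO_Ag replicate 1 (0.273, 0.0644, 0.262, 0.968 and 0.269), platelets also without KO_Ag_IL18 replicate 1 (0.094), macrophage, cholesterol and glycolysis without KO_Ag_IL18 replicate 2 (0.12, 0.177 and 0.609), and cholesterol without KO_Ag_IL18 replicate 3 (0.504). Within a genotype the IL-1β and IL-18 comparisons share the antigen libraries, so lists that passed in both are not independent results. No gene had a detectably different IL-18 response between genotypes by edgeR (919 at an unadjusted p under 0.05; DESeq2 1; 3 genes without KO_Ag replicate 2).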

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

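The responses given first were picked out because they differed between knockout and WT cultures in a test of the difference itself, and the 3 patterns at the end after their values were seen. The tests of other splits, immunoglobulin alleles, B cells, plasma cells and gene length were chosen only after the results were seen. The antigen response differed for 1183 genes. In knockout it was more positive for Ccl12 by 2.45, Gzmb by 2.12, Rasgrp3 by 1.86, Prf1 by 1.88, Gzma by 2.31, Gzmc by 2.71, Nfkbiz by 0.61, Ccnb2 by 1.08 and Ccna2 by 0.97 on the log2 scale. Of these, Rasgrp3, Ccnb2 and Ccna2 fell with antigen and fell less in knockout. The difference was -2.36 for Nes, -2.31 for Fn1, -2.07 for Slpi, -1.66 for Samd4, -1.34 for Fgfr1 and -0.62 for Map1lc3a. Of 100 splits of the 12 libraries 2 gave as many genes, the real one included. The highest other split gave 1528 genes and exchanged the genotype of 4 of the 6 libraries with antigen, so that part of the genotype difference entered the count. Most other splits mix genotypes within a group, which widens the spread (median count 0), so the share does not exclude chance for a difference of responses.

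Cell division genes mostly fell with antigen in both genotypes, and fell less in knockout (median difference 0.749). Cytotoxic genes had a more positive response in knockout (1.212). The lists of cell division and cytotoxic genes held with an estimated correlation. Those for T cells (0.406), NF-kB targets (0.314), type I interferon (0.8), interferon gamma (0.721), MHC class I (0.248), costimulation (0.257), lysosome (-0.111), autophagy (-0.129) and cholesterol synthesis (-0.123) did not (adjusted p = 0.257 to adjusted p = 0.618 with an estimated correlation). Leaving out 1 library ended 4 of these calls: NF-kB without WT_none replicate 2 (adjusted p 0.0839) or KO_none replicate 1 (0.0573), MHC class I without KO_none replicate 1 (0.129), cholesterol without KO_Ag replicate 1 (0.0941), and costimulation without KO_none replicate 1 or 3 (0.296, 0.0803), KO_Ag replicate 1, 2 or 3 (0.0557, 0.0545, 0.0513), WT_Ag replicate 3 (0.0615) or WT_none replicate 2 (0.0609).

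No gene differed in its cytokine response by edgeR (576 for IL-1β and 919 for IL-18 at an unadjusted p under 0.05; DESeq2 0 and 1), yet 7 lists did in each case with a preset correlation, none with an estimated one. For IL-1β these were macrophage (0.09), neutrophil (0.475) and platelet markers (0.454), MHC class II (0.363), cell division (-0.064), glycolysis and hypoxia (-0.095) and cholesterol synthesis (0.081; adjusted p = 0.0963 for neutrophil markers to adjusted p = 0.798 with an estimated correlation). Of these, neutrophil markers alone passed whichever library was left out. Without KO_Ag replicate 1 the others had adjusted p of 0.381, 0.0964, 0.402, 0.111, 0.278 and 0.852 in that order. Macrophage markers were lost also without WT_Ag replicate 2 (0.0515) or KO_Ag_IL1b replicate 2 (0.0747), platelets without WT_Ag replicate 3 (0.0645), MHC class II without WT_Ag replicate 2 or 3 (0.0515, 0.0645), glycolysis without WT_Ag replicate 2 (0.238), WT_Ag_IL1b replicate 1 (0.195) or KO_Ag_IL1b replicate 2 (0.627), and cholesterol without WT_Ag replicate 2 or 3 (0.0812, 0.0645) or KO_Ag_IL1b replicate 2 (0.0732). For IL-18 the lists were B cell (0.402), macrophage (0.146), neutrophil (0.509) and platelet markers (0.588), MHC class II (0.585), cell division (-0.065) and cholesterol synthesis (0.168; adjusted p = 0.181 to adjusted p = 0.453 with an estimated correlation). B cell markers were lost without WT_Ag_IL18 replicate 2 (0.0527) or KO_Ag_IL18 replicate 3 (0.0515) and cholesterol without KO_Ag replicate 1 (0.0557). The IL-1β and IL-18 differences use the same WT_Ag and KO_Ag libraries, so lists that passed for both cytokines are not independent results. All 100 of 100 splits gave at least the real count of 0 genes for IL-1β and for IL-18, and the highest other splits, with 1462 and 2319 genes, exchanged the genotype of all 6 libraries of 1 condition and 2 of the other.

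For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. Every other split also mixed the groups compared, which widens the spread where they differ. A low count in those splits therefore does not exclude chance. Knockout against WT without antigen gave 2379 genes against 12 in the highest other split, 1 of 10 splits reaching the real count; with antigen 2160 against 1, with IL-1β added 1941 against 0 and with IL-18 added 2851 against 0, 1 of 10 each. Antigen gave 9591 against 0 in WT and 9633 against 2 in knockout, IL-1β 8 against 0 and 6 against 3, and IL-18 in knockout 30 against 26, again 1 of 10 each. IL-18 in WT gave 0 by edgeR (580 at an unadjusted p under 0.05; DESeq2 0) against 0, so that 10 of 10 reached it.

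Immunoglobulin RNA was 5.64 higher for Igkc on the log2 scale in knockout cultures without antigen. Alleles of variable regions that differ from the reference are argued against by Jchain, which lies outside these loci and had a log2 fold change of at least 4.5 in the 4 conditions (highest SE 0.233). More B cells are argued against by their markers, of which 1 of 12, Cd22, was higher in all 12 knockout than in all 12 WT libraries. More plasma cells stay open, since 3 of 9 plasma cell markers outside these loci, Jchain, Mzb1 and Derl3, were higher in all knockout libraries; the bound of 3 was set after the values were seen. A candidate explanation is thus a larger share of plasma cell RNA in the knockout arm, whether from genotype or from the lymphocytes used; the design does not separate these where each arm had its own cells.

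Outside the immunoglobulin genes, 406 genes with a known place were called in 1 direction in all 4 genotype comparisons. DNA of another strain kept around Tmem175 was neither shown nor ruled out by the 100 tested genes nearest to it in RefSeq order, of which 4 were such genes (4% against 3.12% of 12858 others, one-sided Fisher's exact p 0.381, odds ratio 1.29, 95% interval 0.344 to 3.45). Gm15446, Zfp932 and Zfp951, picked after their values were seen, lie 8, 9 and 36 tested genes away; Gm15446 stood at 7.91 ± 0.487 CPM in KO_none and 0.0493 ± 0.0492 in WT_none. Such genes were next to each other in 23 pairs, against a median of 13 and a highest of 27 in 10000 random draws (p 0.0041), so blocks of other strain DNA elsewhere stay open. Several pairs are related genes that may change together for other reasons, such as Col4a1 with Col4a2 and Ctsk with Ctss.

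The IL-18 calls in knockout cultures went with transcript length: the 23 lower genes had a median length of 10546 bases and the 7 higher genes of 2004. With the length trend removed, 0 of the 30 calls were left (edgeR; 1321 genes at an unadjusted p under 0.05; DESeq2, run without the correction, 232), and their median absolute log2 fold change went from 0.219 (quartiles 0.198 and 0.25) to 0.146 (0.12 and 0.181). Across genes, which are not independent replicates, the log2 fold changes fell with length in this comparison (Spearman -0.235). They also fell in others, such as IL-18 in WT (-0.125) and IL-1β in WT (-0.107). The difference in IL-1β response went the other way (0.0253). A length bias between libraries, for example from RNA quality, and a response of long genes to IL-18 cannot be told apart, since the correction removes either.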

How the results depend on the processing

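The gene length correction and the counts without immunoglobulin genes were chosen after the results were seen, and the other alternatives before. The genotype and antigen counts stayed within 1.5 times their value under every alternative run except 1: the genotype count with antigen and IL-18, 2851, was 1867 without WT_Ag_IL18 replicate 3 (range 1867 to 2562 over the libraries left out). The other ranges were 1651 to 2624 without antigen, 1642 to 1939 with antigen, 1321 to 1724 with antigen and IL-1β, 9189 to 9271 and 9141 to 9414 for antigen in WT and knockout, and 819 to 1697 for the difference in antigen response. With a replicate block these counts were 2876, 2636, 2372 and 3437 for genotype, 9826 and 9842 for antigen and 1596 for the difference. Without immunoglobulin genes the 4 genotype counts were 2145, 1934, 1699 and 2621, and the difference in antigen response 1184.

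The counts for IL-1β in both genotypes and for IL-18 in knockout moved by more than 1.5 times with most choices, whereas the other 3 cytokine counts stayed at 0 with most; the cause was not tested. For IL-1β in WT (8) the count was 79 without a filter, 102 with a replicate block, 46 from the compared libraries alone and 2 to 7 over the libraries left out. For IL-1β in knockout (6) it was 73 with DESeq2, 287 without a filter, 422 with a block and 1 to 284 over the libraries left out. For IL-18 in WT (0; 580 at an unadjusted p under 0.05; DESeq2 0) it was 2 without a filter, 1 with a block, 2 from the compared libraries alone and 0 to 1 over the libraries left out. For IL-18 in knockout (30) it was 232 with DESeq2, 302 without a filter, 274 with a block, 0 with the length trend removed, 0 from the compared libraries alone and 0 to 233 over the libraries left out. For the differences in response between genotypes, IL-1β (0) gave 1 without a filter and 0 in every fit with a library left out, and IL-18 (0) gave 1 with DESeq2, 17 without a filter, 5 with a block and 0 to 3 over the libraries left out.

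The replicate numbers carried a signal: 30 of 84 pairs of libraries with the same number in different groups had a residual correlation above 0.1 (median 0.0729, from -0.0452 to 0.276), and 21 of 24 libraries correlated best with their own number. Pairs with different numbers had a median of -0.0449 and 4 of 168 above 0.1. The medians were 0.0624, 0.139 and 0.0285 for numbers 1, 2 and 3. Since not every pair with the same number was above 0.1, the main fit did not treat the numbers as pairs. That bound does not show that the numbers are unpaired. With a replicate block the IL-1β counts went from 8 to 102 in WT and from 6 to 422 in knockout. Of 116 list calls 8 held with a correlation estimated from the data; fry made 127 calls but kept 66 of the 116, lost 50 and gained 61. A replicate block made 136 and kept 115, and leaving out 1 library gave 103 to 125, the lowest without KO_Ag replicate 1, where 20 of 57 calls that use it were lost. The 8 were cell division in the 4 genotype comparisons and the difference in antigen response, cytotoxic genes without antigen and in that difference, and plasma cell markers without antigen. The cholesterol list after IL-18 in knockout was the only called result to change direction: it pointed up with all libraries, and without KO_Ag replicate 1 it pointed down (adjusted p 0.968). It was lost also without KO_Ag_IL18 replicate 2 (0.177) or 3 (0.504), and over the libraries left out its adjusted p ran from 2.64e-05 to 0.968; the cause was not tested.

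Of 963 results for named genes 810 were called and none reversed. Median-of-ratios factors kept 808 of these calls, DESeq2 757, no filter 771, a block 810 and the length correction 772; 610 held whichever library was left out, and 683 of 792 held in the compared libraries alone. The block added 7 calls of named genes, among them Gzmb between genotypes with antigen (adjusted p 0.0185), Il18 after IL-1β in knockout (0.0241) and the difference in antigen response of Il1rn (0.0104), and ended the call of the type 2 and type 17 T cell list between genotypes with antigen (0.0549). Depth limits genes near 3 counts per library, for which CPM values stand in place of folds. At these spreads 38% of true 1.2-fold changes were found on simulated counts, so cytokine effects of that size were often beyond detection. The simulated comparison had 177 called genes, against at most 30 in the real cytokine comparisons in the main fit. Adjustment is stricter where fewer genes change, so 38% may be too high there.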

Other observations

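The genes named in this part were picked after their values were seen and lie outside the rule for naming genes, except Lyz2 and Adgre1. The 2 tests of a shared lymphocyte pool were written down before their values were seen, and only the spread with 1 library left out was chosen after. The 2 lysozyme genes, which are neighbours, moved in opposite directions between genotypes. Lyz1 stood at 6.84 ± 0.372, 16.8 ± 1.46, 16.1 ± 0.573 and 13.7 ± 2.92 CPM in WT cultures without antigen, with antigen, and with IL-1β or IL-18 added, and at 34.3 ± 5.21, 64.1 ± 6.28, 73.8 ± 4.61 and 79.7 ± 10.3 in knockout cultures. Lyz2, the lysozyme of macrophages, stood at 11300 ± 333, 14800 ± 532, 15000 ± 195 and 14100 ± 922 CPM in WT and at 6080 ± 178, 6850 ± 768, 8010 ± 282 and 7680 ± 346 in knockout. Gm42031 stood at 26.4 ± 1.77, 9.42 ± 0.72, 10.6 ± 1.42 and 9.98 ± 0.236 CPM in WT cultures in the same order and at no more than 0.153 in knockout cultures.

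T cell RNA was scarce in all groups. Cd3e had group means of 0.925 to 1.87 CPM and Trac of 1.18 to 2.04, whereas the macrophage gene Adgre1 had 1450 to 4790. The B cell gene Cd22 stood at 41.2, 37.6, 35.7 and 35.2 CPM in WT and 60.2, 45.5, 45.2 and 44.7 in knockout cultures. Zfp932 rose with antigen in knockout cultures from 13.2 ± 0.955 to 22 ± 1.02 CPM, against 9.75 ± 0.56 to 11.9 ± 1.13 in WT, and Zfp951 was at 6.42 ± 0.585 in KO_none against 3.21 ± 0.412 in WT_none.

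The variable segments of immunoglobulin genes give a mark of the lymphocytes in each culture. Among knockout libraries of different groups the lowest correlation over 185 segments was 0.963 in 54 pairs as deposited, which goes with 1 lymphocyte pool for these cultures. At an equal depth of 663 counts per library these pairs ran from 0.644 to 0.777, next to 0.426 to 0.636 among WT libraries. What separate pools would give at these depths was not measured, so 1 pool for the knockout arm is not established. At that depth WT libraries correlated with knockout libraries less than with WT libraries of other groups (medians 0.434 and 0.547), a difference of -0.113. With 1 library left out the difference ran from -0.128 to -0.102, all beyond the bound of -0.1 set beforehand, though by little. As deposited, the medians were 0.545 and 0.587. A separate pool for each genotype is thus a candidate explanation for the immunoglobulin difference that has no need of Tmem175. A change of the plasma cells themselves with genotype could also alter segment use, and was not tested. Co-cultures of both genotypes with lymphocytes of the same spleen, or macrophages without lymphocytes, could tell the explanations apart.

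The chi-square per degree of freedom between replicates, used here to compare pairs of libraries and not as a test, ran from 2.97 to 16.7 in the knockout groups and from 1.47 to 5.27 in the WT groups. In groups of both genotypes 1 library was farther from the others. Replicate 2 of KO_none gave 16.7 and 10.5 against the others, which differed by 3.18. Replicate 1 of KO_Ag gave 10.1 and 5.5 (the others 3.03), replicate 2 of KO_Ag_IL1b 10.4 and 5.29 (2.97), and replicate 1 of KO_Ag_IL18 9.08 and 5.87 (3.7). Replicate 2 of WT_none gave 3.79 and 3 (1.47), and replicate 2 of WT_Ag_IL1b 3.42 and 2.81 (1.86).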
